A study of Homo sapiens with 12 samples.

How the data were processed

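Libraries were made from MCF-7 cells grown in phenol red-free medium with charcoal-stripped serum and treated in 6 groups of 2 replicates. Per the labels' protocols, 500 ng of total RNA per sample went into a 3′ mRNA kit (QuantSeq), with oligo-dT priming, reverse transcription, random-primed second strand synthesis and 16 cycles of PCR, so reads come from the 3′ ends of polyadenylated transcripts. Molecular identifiers are not named in the sources used here, so PCR copies could not be removed. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The Vehicle group's exposure time is not given in the sources used here.

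The deposited table holds 26549 genes with their RefSeq identifier and hg38 position. Per the file headers and the submitters' processing notes, the authors counted reads with HOMER over the gene body and compared groups with edgeR on hg38; versions, the aligner, the strand setting and the RefSeq release are not given in the sources used here. The deposited signal values are read counts that the authors scaled so that every library sums to about the same total (20716709 in Vehicle replicate 1). The scale factor of each library could be recovered from the low values, and dividing by it gave whole reads for 100% of values in the 12 libraries, within 0.1 of a whole number; in Vehicle replicate 1 and R4K1 replicate 1 the factor was too close to 1 for that test to mean much on low values. Recovered totals ran from 15929824 (4OHT replicate 2) to 24086978 (E2+4OHT replicate 2). The 10 most abundant genes took 4.48% to 7.66% of the reads.

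The authors also deposited a log2 change and a p-value for each of 15 pairs of groups, per the file headers; whether the p-value is adjusted is not stated, and these p-values were not used here. Across genes, the authors' deposited log2 changes and those computed here had Pearson correlations of 0.965 to 0.992 in 9 comparisons. One gene symbol occurred more than once and 1 of its entries was kept, leaving 26548 genes. Mitochondrial transcripts were not analysed here, so a list of 15 of them gave no result. IDI1 and the antisense gene IDI2-AS1, on opposite strands, had counts in a ratio of 1.014 to 1.08 in the 12 libraries, so overlapping and antisense genes were treated as uncertain. Of the genes named with values, this applies to RNF43, NTN4 and THSD4-AS1.

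Before the data were examined, the groups, the comparisons, the rule for named genes, 22 gene lists and the alternatives were fixed. The planned test was edgeR on deposited counts. Because the deposited unit is scaled counts and not counts, limma 3.58.1 on log2 values was used instead. Both tools had been run once on these data in exploration before the choice was settled on the unit. Values were scaled with TMM factors, 1 was added, and log2 taken; fold changes are on this log2(value + 1) scale, which understates the change of low genes. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17301. All 12 libraries entered 1 fit with a mean per group, 6 residual degrees of freedom and one shared estimate of spread (empirical Bayes with a trend and robust settings), and p-values were adjusted by the Benjamini-Hochberg method within each of 11 comparisons. A gene was called at an adjusted p below 0.05. Comparisons were each treatment against Vehicle, each inhibitor with E2 against E2, E2 with each inhibitor against that inhibitor, the inhibitors against each other with and without E2, and the 2 interactions, in which the E2 response without inhibitor is subtracted from that with it.

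Of the gene lists 21 were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the residuals, and with fry, all two-sided and adjusted over the lists of a comparison. Camera asks whether a list changed more than the other genes, and fry whether the list itself changed. They cover estrogen-induced and estrogen-repressed genes, the receptor and its cofactors, immediate early genes, cholesterol synthesis, ATF4 targets, endoplasmic reticulum stress, heat shock, NRF2, lysosome, interferon, inflammatory genes, DNA replication, mitosis, ribosome biogenesis, p53, hypoxia, aryl hydrocarbon receptor, luminal, basal and mesenchymal genes, and markers of other cell types. Named genes were, per comparison, the 10 raised and the 10 lowered with the largest change among called genes with a mean log2 CPM of at least 2, 8 estrogen response genes in every comparison (ESR1, GREB1, TFF1, PGR, MYC, CCND1, CXCL12 and SIAH2), and up to 4 members of each list; the text names part of them. Overlaps of calls between comparisons with the same controls were set beside 100 simulations of unchanged groups. Held-out responses used genes with at least a 2-fold change in 1 replicate and a mean log2 value of at least 6.

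On simulated counts for E2 against Vehicle with 17098 genes, limma recovered 42% of 1.5-fold and 70.7% of 2-fold changes, and 11 of 123 called genes had not been changed. Alternatives were other scaling (RLE factors, library totals), no filter (23004 genes) or a filter at 5 CPM in 2 libraries (12607 genes), pseudocounts of 0.25 and 8, DESeq2 1.42.0 and edgeR 4.0.16 on recovered reads, only the groups compared, the replicate number as a factor, every deposited entry, no RNA45S5, small nucleolar, small nuclear and histone genes, and each library left out in turn. The pseudocounts, edgeR on recovered reads, the removal of RNA classes, the thinning of reads to 15929818 per library and the recomputing of lists (by all 3 tests) and overlaps were added after the data were seen. Where a library was left out, the remaining one of its group was assumed to vary like the other groups. R 4.3.3 and Python 3.11.15 were used.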

Results

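The data were 12 RNA sequencing libraries of MCF-7 cells, an estrogen receptor-positive human breast cancer line, in 6 groups of 2 replicates each. Cells kept in hormone-depleted medium received DMSO (Vehicle), 10 nM estradiol (E2, the natural ligand of the estrogen receptor) for 2 h, 1 µM 4-hydroxytamoxifen (4OHT, a receptor antagonist in breast cells) for 2 h, or 15 µM R4K1, a stapled peptide, for 24 h. In the E2+4OHT group 4OHT preceded E2 by 2 h, and in the E2+R4K1 group the peptide preceded E2 by 24 h, so the exposures to the 2 inhibitors differed in length as well as in dose. Cells of the E2+4OHT group were also exposed to 4OHT for longer than those of the 4OHT group, so comparisons of these 2 groups mix E2 with that difference. Libraries held 15929824 to 24086978 reads in genes, and 17301 genes were tested. Changes are given on the log2 scale with their standard error, levels as scaled counts with their SD, and n = 2 per group throughout.

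The R4K1 replicates differed most, with an SD of log2 differences of 0.380, against 0.235 to 0.283 in the other 5 groups. The ribosomal precursor RNA45S5 took 1.90% of the reads in R4K1 replicate 1 and 0.044% in R4K1 replicate 2, with 0.508% to 1.19% in the other 10 libraries. Small nucleolar RNA genes lay at a median of 0.22 in replicate 1 and −0.54 in replicate 2 from the mean of the other groups, and protein-coding genes at 0 and 0.01. One shared spread is too small for the R4K1 group, so its standard errors and p-values are too optimistic. Counts that rest on it are also given without each R4K1 library, as are list results that moved most.

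Estradiol raised the textbook estrogen targets within 2 h. GREB1, a growth regulator bound by the receptor (NM_014668, hg38 chromosome 2: 11534116–11642786, plus strand), rose by 2.10 ± 0.09 (adjusted p = 2.06e-09), from 3091 ± 152 to 13240 ± 149 scaled counts. PGR, the progesterone receptor gene (NM_000926, chromosome 11: 101029624–101129813, minus strand), rose by 2.86 ± 0.15 (adjusted p = 3.87e-09), from 150.4 ± 29.7 to 1091 ± 45.1. The cell adhesion gene SDK2 rose by 3.21 ± 0.16 and the transcription factor genes FOXC1 and EGR3 by 2.75 ± 0.14 and 2.74 ± 0.22. The ubiquitin ligase gene SIAH2 rose by 1.79 ± 0.12, MYC by 1.59 ± 0.16, the chemokine gene CXCL12 by 1.48 ± 0.16, the secreted trefoil peptide gene TFF1 by 0.89 ± 0.12 and the cyclin gene CCND1 by 0.61 ± 0.08. TNFRSF11B, which encodes the decoy receptor osteoprotegerin, fell by 2.27 ± 0.17 on the log2 scale. The receptor gene itself, ESR1 (NM_001122742, chromosome 6: 151690496–152103273, plus strand), stood at −0.28 ± 0.08 (adjusted p = 0.0623). It was called without R4K1 replicate 1 or 2 (0.00293 and 0.00277), with the 4 compared libraries alone (0.00164) and with DESeq2 (0.0297).

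Of the 49 measured members of the estrogen-induced list, 40 rose with E2, 1 fell (GAREM1, −0.48, named after its value was seen) and 8 were not called. When adjusted over the list alone, 42 rose and 1 fell. The list's median change was 1.18 (camera's adjusted p = 2.5e-69), and CA12, a carbonic anhydrase gene, rose by 1.54 ± 0.07 within it. The estrogen-repressed list of 20 had a median of −0.41, with 6 members lower, 2 higher and 12 not called (adjusted over the list alone, 11 lower and 2 higher; camera's adjusted p = 1.55e-06). CCNG2, a cyclin of cell cycle exit, fell by 1.00 ± 0.10 in this list, whereas the transcriptional repressor gene HES1 rose by 0.64. Among 28 ribosome biogenesis genes, 11 rose, 0 fell and 17 were not called (adjusted over the list alone, 16 rose, with a median of 0.34, camera's adjusted p = 8.12e-12), with RCL1, a ribosomal RNA processing factor, up by 0.58 ± 0.08. These 3 lists were also called with an estimated correlation between members (adjusted p = 0.00219, 0.0278 and 0.0048). There the repressed list was not called without Vehicle replicate 1 or 2 (0.0795 and 0.0892), E2 replicate 1 (0.0618) or R4K1 replicate 1 or 2 (0.169 and 0.168). No interferon gene was called among 19 (median −0.27; adjusted over the list alone, 0), and camera's adjusted p of 0.0256 became an adjusted p = 0.165 with an estimated correlation and 0.128 without Vehicle replicate 1. In the p53 list of 22, 4 fell, 2 rose and 16 were not called (adjusted over the list alone, 7 and 2, with a median of −0.12). Its camera adjusted p was 0.027, against an adjusted p = 0.165 with an estimated correlation, 0.128 without Vehicle replicate 1 and 0.109 without E2 replicate 1. Fry called both of these lists (adjusted p = 0.0169 and 0.00281), interferon not without Vehicle replicate 1 (0.0836) or E2 replicate 1 or 2 (0.0571 and 0.0715).

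In limma's test 903 genes were called between E2 and Vehicle, 645 higher and 258 lower, of which 195 and 38 changed at least 2-fold. The count was 445 and 460 without E2 replicates 1 and 2, 491 and 514 without Vehicle replicates 1 and 2, and 1646 and 1660 without R4K1 replicates 1 and 2, whose spread widens the shared error. With the spread taken from the 4 compared libraries alone it was 1655.

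**Figure D1:**
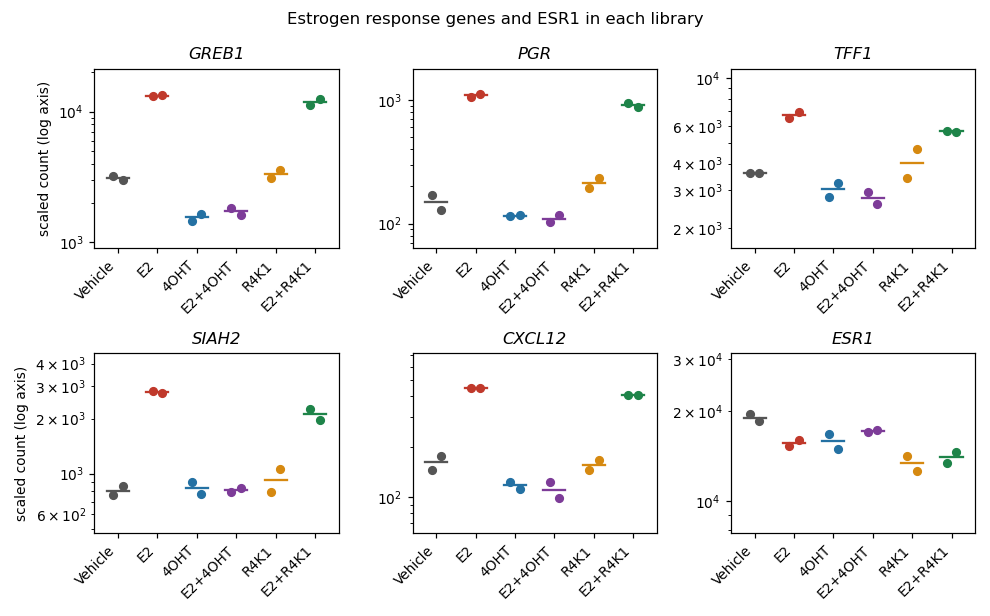
Scaled counts per library on a log axis for GREB1, PGR, TFF1, SIAH2, CXCL12 and ESR1 in the 6 groups, with each library as a point and the group mean as a line. GREB1 averaged 13240 with E2, 1719.9 with E2+4OHT and 11913 with E2+R4K1.

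With 4OHT alone, stress, sterol and xenobiotic genes rose within 2 h. CYP1A1, a cytochrome induced through the aryl hydrocarbon receptor (NM_000499, chromosome 15: 74719542–74725536, minus strand), rose by 7.12 ± 0.39 (adjusted p = 6.69e-07), from 23 ± 0.276 to 3286 ± 220 scaled counts, and its relative CYP1B1 rose by 4.26 ± 0.17. CHAC1, a glutathione-degrading enzyme induced by ATF4, rose by 4.24 ± 0.19 (adjusted p = 5.41e-10). The stress genes ATF3, GDF15 and DDIT4 rose by 2.49 ± 0.20, 2.33 ± 0.13 and 2.17 ± 0.14, and HMGCS1, an early enzyme of cholesterol synthesis, by 1.84 ± 0.08. MYC rose by 1.06 ± 0.16, whereas GREB1 fell by 0.98 ± 0.09 on the log2 scale, the sterol transporter gene ABCG1 by 1.33 ± 0.12 and the growth factor binding protein gene IGFBP5 by 1.02 ± 0.11. PGR (−0.33), TFF1 (−0.23), CXCL12 (−0.43), ESR1 (−0.24), CCND1 (0.21) and SIAH2 (0.07) were not called, with adjusted p between 0.094 and 0.806. Without R4K1 replicate 1 or 2, ESR1 (0.013 and 0.0126), TFF1 (0.0391 and 0.0388), CXCL12 (0.0456 and 0.0464) and CCND1 (0.014 and 0.0137) were called in the same direction, and in the 4 compared libraries alone ESR1 (0.0278) and TFF1 (0.049).

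Among the fixed lists, stress and metabolic ones were higher with 4OHT than with Vehicle. In the cholesterol synthesis list 20 of 25 members rose and 5 were not called (adjusted over the list alone, 21, with a median of 1.04, camera's adjusted p = 1.91e-32). Of 22 ATF4 target genes 18 rose and 4 were not called (adjusted over the list alone, 18, with a median of 1.15, adjusted p = 4.15e-35). In the endoplasmic reticulum stress list 14 of 19 rose and 5 were not called (adjusted over the list alone, 17, with a median of 0.65, adjusted p = 3.61e-22), with the chaperone gene HSPA5 up by 0.96 ± 0.07. Of 9 aryl hydrocarbon receptor genes 8 rose and 1 was not called (adjusted over the list alone, 9, with a median of 1.20, adjusted p = 1.01e-16). Of 19 NRF2 genes 9 rose and 10 were not called (adjusted over the list alone, 10, with a median of 0.29, adjusted p = 3.55e-11). Ribosome biogenesis had 7 of 28 higher and 21 not called (adjusted over the list alone, 9 higher and 1 lower, with a median of 0.20, adjusted p = 1.61e-05). All 6 were called with an estimated correlation, with adjusted p between 0.000843 and 0.0163, ribosome biogenesis not without Vehicle replicate 2 (0.0551).

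Camera called other lists for 4OHT with the preset correlation and not with an estimated one. Immediate early genes had 9 of 33 higher, 0 lower and 24 not called (adjusted over the list alone, 13 and 1, with a median of 0.21, adjusted p = 4.75e-06, and adjusted p = 0.162 with an estimated correlation). Heat shock genes had 3 of 17 higher and 14 not called (adjusted over the list alone, 3, with a median of 0.11, adjusted p = 0.0456, and adjusted p = 0.162 with an estimated correlation, 0.123 without Vehicle replicate 1 and 0.215 without 4OHT replicate 2). No interferon gene of 19 was called (adjusted over the list alone, 0, with a median of −0.38, adjusted p = 0.0022, and adjusted p = 0.0647 with an estimated correlation). DNA replication genes had 4 of 28 lower, 1 higher and 23 not called (adjusted over the list alone, 6 and 1, with a median of −0.12, adjusted p = 0.00134, and adjusted p = 0.143 with an estimated correlation). Mitosis genes had 3 of 25 lower and 22 not called (adjusted over the list alone, 3, with a median of −0.12, adjusted p = 0.00801, and adjusted p = 0.273 with an estimated correlation). Left-out libraries brought the estimated-correlation p of interferon to 0.0276 (4OHT replicate 1) and of DNA replication to 0.0464 (Vehicle replicate 1). Fry called immediate early (adjusted p = 0.00257), heat shock (0.0215), interferon (0.00229) and DNA replication genes (0.0165) and not mitosis genes (0.0876). It lost heat shock without Vehicle replicate 1 (0.0538) or 4OHT replicate 2 (0.122), and DNA replication without Vehicle replicate 2 (0.111) or 4OHT replicate 1 (0.0723). Camera called neither the estrogen-induced list (8 higher and 1 lower of 49, and adjusted over the list alone, 10 and 5; median 0.03, adjusted p = 0.36) nor the hypoxia (0.081), lysosome (0.378), p53 (0.081), luminal (0.884) and inflammatory (0.521) lists, of which fry called hypoxia (0.00229) and p53 (0.00258), and camera both without Vehicle replicate 1 (0.0435 and 0.0486).

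Between 4OHT and Vehicle 1378 genes were called, 924 higher and 454 lower, and 157 and 63 of them changed at least 2-fold. Without replicates 1 and 2 in turn the count was 496 and 711 (4OHT), 530 and 770 (Vehicle) and 2983 and 2985 (R4K1), and it was 2315 with the 4 compared libraries alone.

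**Figure D2:**
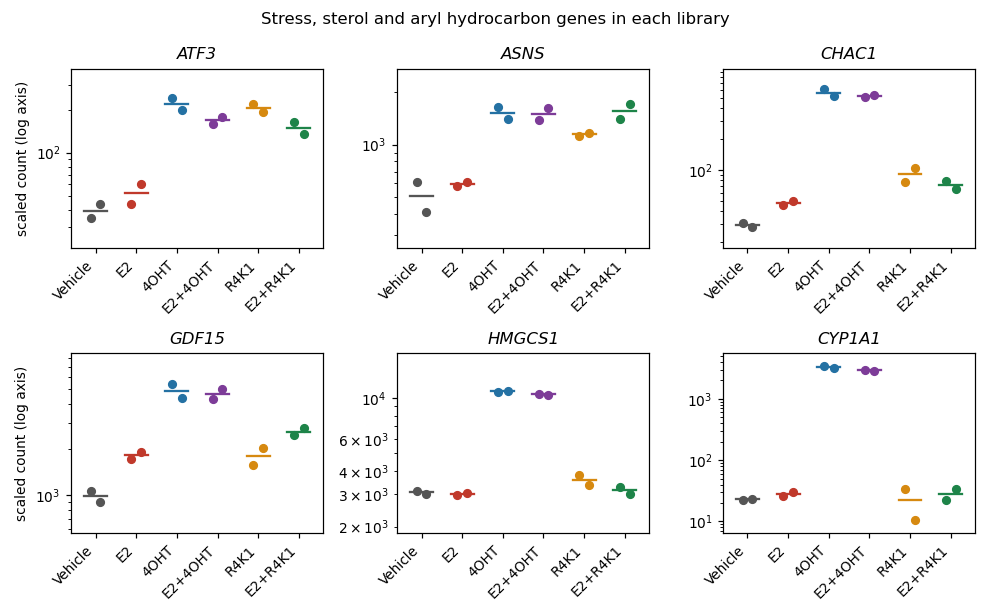
Scaled counts per library on a log axis for ATF3, ASNS, CHAC1, GDF15, HMGCS1 and CYP1A1 in the 6 groups, with each library as a point and the group mean as a line. CYP1A1 averaged 3285.9 with 4OHT and 22.15 with R4K1, while ATF3 averaged 220.03 and 205.33.

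Given before E2, 4OHT brought estrogen targets below their level with E2 alone. PGR fell by 3.32 ± 0.15 on the log2 scale (adjusted p = 3.83e-10), to 109.6 ± 10.5 scaled counts, and GREB1 by 2.96 ± 0.09 (adjusted p = 1.13e-11), to 1720 ± 136. CXCL12 fell by 2.03 ± 0.16 on that scale, SIAH2 by 1.80 ± 0.12, TFF1 by 1.29 ± 0.12, MYC by 1.10 ± 0.16 and CCND1 by 0.53 ± 0.08. CYP1A1, CHAC1 and HMGCS1 rose by 6.65 ± 0.39, 3.41 ± 0.19 and 1.78 ± 0.08. In the estrogen-induced list 38 of 49 members fell, 4 rose and 7 were not called (adjusted over the list alone, 42 and 4, with a median of −0.99, camera's adjusted p = 2.79e-35). Ribosome biogenesis had 6 of 28 lower and 22 not called (adjusted over the list alone, 7, with a median of −0.15, adjusted p = 0.000373). Cholesterol synthesis genes rose in 21 of 25 cases with 4 not called (adjusted over the list alone, 21, with a median of 0.97, adjusted p = 7.28e-29). ATF4 genes rose in 18 of 22 cases with 4 not called (adjusted over the list alone, 19, with a median of 0.96, adjusted p = 7.65e-31), and NRF2 genes in 7 of 19 with 12 not called (adjusted over the list alone, 7, with a median of 0.10, adjusted p = 3.48e-06). Of the endoplasmic reticulum stress genes 12 of 19 rose, 1 fell and 6 were not called (adjusted over the list alone, 14 and 1, with a median of 0.50, adjusted p = 2.44e-12). Of the aryl hydrocarbon receptor genes 7 of 9 rose, 1 fell and 1 was not called (adjusted over the list alone, 7 and 1, with a median of 0.86, adjusted p = 2.37e-09). Each of the 7 was called with an estimated correlation (adjusted p between 0.00126 and 0.0449). There endoplasmic reticulum stress was lost when any 1 of the 10 libraries outside the E2+R4K1 group was left out (0.0524 to 0.0771, with 0.0618 for either R4K1 library). Ribosome biogenesis was lost when any Vehicle, E2 or E2+4OHT library was (0.0522 to 0.0685).

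In limma's test 1998 genes were called between E2+4OHT and E2, 1099 higher and 899 lower. Without replicates 1 and 2 in turn the count was 3501 and 3499 (R4K1), 1000 and 1058 (E2) and 1042 and 1001 (E2+4OHT), and the 4 compared libraries alone gave 4935.

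Between E2+4OHT and 4OHT, which differ in E2 and in the time with 4OHT, no single gene was called. GREB1 stood at 0.12 ± 0.09 (adjusted p = 0.798), PGR at −0.12 ± 0.15 (0.881), MYC at −0.57 ± 0.16 (0.456), TFF1 at −0.16 (0.771), CXCL12 at −0.13 (0.881), CCND1 at −0.13 (0.693), SIAH2 at −0.07 (0.924) and ESR1 at 0.07 (0.869). In the 4 compared libraries alone MYC was called (0.00826). The 645 genes that E2 raised without inhibitor had a median of 0.68 there and 0.05 here, with 394 (61.1%) in the same direction, and the 258 lowered genes had −0.59 and 0.00, with 130 (50.4%) in the same direction. Fry's adjusted p was 0.0147 for the raised set and 0.701 for the lowered set. With a library left out, the sets were chosen anew from that fit's calls and so held other genes. The raised set's median then ran from 0.03 to 0.09, and its call was lost in 5 of these fits. They were those without Vehicle replicate 2, 4OHT replicate 2, E2+4OHT replicate 1, R4K1 replicate 1 or R4K1 replicate 2. Limma called 0 genes between E2+4OHT and 4OHT, with 1396 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0736. EdgeR called 0 genes and DESeq2 3. Limma called 1 gene without 4OHT replicate 1, 51 and 52 without R4K1 replicates 1 and 2, and 337 in the 4 compared libraries alone.

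The difference between the 2 responses was tested as an interaction, which holds the same difference in time. The E2 response of PGR was smaller after 4OHT, with an interaction of −2.98 ± 0.21 (adjusted p = 6.88e-07), as was that of GREB1 with one of −1.98 ± 0.13 (adjusted p = 6.88e-07). The same held for MYC (−2.16, adjusted p = 2.21e-05), SIAH2 (−1.86, adjusted p = 8.93e-06), CXCL12 (−1.61, adjusted p = 0.000396), TFF1 (−1.05, adjusted p = 0.00213) and CCND1 (−0.74, adjusted p = 0.000608). ESR1 had an interaction of 0.35 that was not called (adjusted p = 0.177, against 0.0132 and 0.0128 without R4K1 replicates 1 and 2 and 0.00687 with the 8 libraries of this test alone). The estrogen-induced list had a median interaction of −1.18, with 34 of 49 members called lower and 15 not called (adjusted over the list alone, 40 lower and 1 higher; camera's adjusted p = 2.58e-68). Ribosome biogenesis had one of −0.46, with 7 of 28 lower and 21 not called (adjusted over the list alone, 13; adjusted p = 3.29e-14). Both calls held with an estimated correlation (adjusted p = 0.00229 and 0.00284). Limma called 388 genes, 102 higher and 286 lower. Without one library at a time the count was 222 and 257 (Vehicle 1 and 2), 195 and 199 (E2 1 and 2), 221 (4OHT 2), 214 and 205 (E2+4OHT 1 and 2), and 863 and 863 (R4K1 1 and 2). It was 947 with the 8 libraries of this test alone.

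Amino acid and oxidative stress genes were higher with R4K1 alone than with Vehicle, a comparison that holds 24 h of exposure with no control stated to match it. ATF3, a stress-induced transcription factor (NM_001030287, chromosome 1: 212565334–212620777, plus strand), rose by 2.43 ± 0.20 (adjusted p = 1.79e-05), from 39.1 ± 6.2 to 205 ± 18.5 scaled counts. CHAC1 rose by 1.64 ± 0.19 (adjusted p = 0.000567), ASNS, which makes asparagine, by 1.26 ± 0.15 (adjusted p = 0.000843), the secreted hormone gene STC2 by 0.95 ± 0.10 and GDF15 by 0.93 ± 0.13, while IGFBP5 fell by 0.93 ± 0.11 on the log2 scale. These 6 calls held without any 1 of the 12 libraries. In the 4 compared libraries alone those of CHAC1 (0.345), GDF15 (0.156) and ASNS, STC2 and IGFBP5 (0.0585 each) were lost. ESR1 fell by 0.45 ± 0.08 on the log2 scale (adjusted p = 0.0146), from 19030 ± 720 to 13400 ± 1140 scaled counts, a call lost without Vehicle replicate 1 (adjusted p = 0.222) or 2 (0.0615) or in the 4 compared libraries alone (0.516). The estrogen targets GREB1 (0.17, adjusted p = 0.378), TFF1 (0.20, 0.411), PGR (0.57, 0.0586), MYC (0.58, 0.0732), CCND1 (0.20), CXCL12 (0.00) and SIAH2 (0.25) were not called. Without R4K1 replicate 1 the changes were larger for GREB1 (0.27), TFF1 (0.42), PGR (0.69), MYC (0.66), CCND1 (0.24) and SIAH2 (0.44). Without Vehicle replicate 2, MYC stood at 0.83. Without R4K1 replicate 2, TFF1 stood at −0.02. DESeq2 called PGR (0.0318) and MYC (0.0392).

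In the ATF4 list 11 of 22 members rose with R4K1 and 11 were not called (adjusted over the list alone, 15, with a median of 0.42, camera's adjusted p = 3.46e-19). Of 19 NRF2 genes 6 rose and 13 were not called (adjusted over the list alone, 11, with a median of 0.25, adjusted p = 5.48e-09). Of 28 ribosome biogenesis genes 5 rose and 23 were not called (adjusted over the list alone, 16, with a median of 0.26, adjusted p = 8.49e-12). Of 17 heat shock genes 2 rose and 15 were not called (adjusted over the list alone, 6, with a median of 0.23, adjusted p = 1.86e-06), against 8 higher without either R4K1 replicate. The estrogen-repressed list was lower, with 2 of 20 lower and 18 not called (adjusted over the list alone, 6, with a median of −0.22, adjusted p = 0.000195). The aryl hydrocarbon receptor list was higher with 0 of 9 called (adjusted over the list alone, 4, with a median of 0.22, adjusted p = 0.00227, lost without R4K1 replicate 1 at 0.148). The 6 lists were called with an estimated correlation too, with adjusted p between 0.00381 and 0.049, and the ATF4 list alone was called whichever library was left out. Without R4K1 replicate 2 the ATF4 list had 13 members higher at the same median of 0.42 (camera's adjusted p = 1.31e-15), and ribosome biogenesis had 12 higher (median 0.32). With R4K1 replicate 1 or 2 left out, NRF2 had 12 and 6 members higher, the repressed list 9 and 3 lower, and the aryl hydrocarbon receptor list 3 higher in each case, with 1 lower in the first. With replicate 2 left out, the estimated-correlation test no longer called heat shock (adjusted p = 0.0885), the repressed list (0.182) or the aryl hydrocarbon receptor list (0.0927). With replicate 1 left out it called none of these 3 (0.25, 0.27 and 0.402), nor NRF2 (0.0755) or ribosome biogenesis (0.0712). The repressed list was also lost when any Vehicle, E2 or E2+4OHT library was left out (0.0585 to 0.159), and the aryl hydrocarbon receptor list when any other library but Vehicle replicate 2 was (0.0508 to 0.133).

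Camera called further lists for R4K1 with the preset correlation and not with an estimated one. The estrogen-induced list had 4 of 49 higher and 45 not called (adjusted over the list alone, 9 higher and 3 lower, with a median of 0.14, adjusted p = 0.00138, and adjusted p = 0.211 with an estimated correlation). Without R4K1 replicate 2 its median was 0.02 (adjusted p = 0.199). It was 0.24 without R4K1 replicate 1, with 20 higher and 5 lower (camera's adjusted p = 0.000231, fry's 0.0067, and adjusted p = 0.15 with an estimated correlation). Immediate early genes had 5 of 33 higher and 28 not called (adjusted over the list alone, 11 and 1, with a median of 0.24, adjusted p = 6.88e-08, and adjusted p = 0.0993 with an estimated correlation), and 13 and 4 higher without R4K1 replicates 1 and 2. DNA replication genes had 2 of 28 higher and 26 not called (adjusted over the list alone, 2, with a median of 0.14, adjusted p = 2.45e-05, and adjusted p = 0.0647 with an estimated correlation). The remaining such lists had 0 members called with all libraries. Mitosis genes had a median of 0.12 (adjusted over the list alone, 0, adjusted p = 0.00565, and adjusted p = 0.239 with an estimated correlation). Cholesterol synthesis genes had one of 0.11 (adjusted over the list alone, 2 higher, adjusted p = 0.0123, and adjusted p = 0.192 with an estimated correlation). Interferon genes had one of −0.20 (adjusted over the list alone, 0, adjusted p = 0.00317, and adjusted p = 0.0665 with an estimated correlation). Camera lost these 3 calls without R4K1 replicate 1 (adjusted p = 0.942, 0.118 and 0.052). There 3 of 25 mitosis genes were higher and 4 lower (median 0.03), 5 of 25 cholesterol genes higher and 1 lower, and 4 of 19 interferon genes lower. Cholesterol had 3 higher and interferon 1 lower without R4K1 replicate 2. Mitosis genes then had a median of 0.24, with 6 higher and 0 lower (adjusted over the list alone, 11, camera's adjusted p = 1.04e-07, and adjusted p = 0.0179 with an estimated correlation). The estimated-correlation test also called immediate early genes without E2+R4K1 replicate 1 or 2 (0.0417 and 0.0416), and DNA replication genes without Vehicle replicate 2 (0.0479) or 4OHT replicate 1 or 2 (0.0335 and 0.0336). Fry called immediate early (adjusted p = 0.0116), DNA replication (0.00658) and interferon genes (0.00658), the first not without Vehicle replicate 1 (0.0615) or R4K1 replicate 2 (0.095). It did not call the other 3 (0.0573 to 0.135).

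Between R4K1 and Vehicle 279 genes were called, 131 higher and 148 lower, with 13 and 15 at least 2-fold. Scaling by library totals gave 78 and 251. The count was 11 and 91 without Vehicle replicates 1 and 2, 3402 and 918 without R4K1 replicates 1 and 2, and 139 to 177 without any 1 of the other 8 libraries. It was 4 with the 4 compared libraries alone, 135 with no filter on low counts and 499 with DESeq2.

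Some ATF4 and NRF2 genes were higher with E2+R4K1 than with E2 alone, and the main estrogen targets were not called. ASNS rose by 1.38 ± 0.15 (adjusted p = 0.000521) over E2 alone. RPRM, a cell cycle arrest gene, fell by 1.14 ± 0.12 on the log2 scale (adjusted p = 0.000408), from 860.2 ± 79.4 to 389 ± 40.7 scaled counts. ATF3 rose by 1.52 ± 0.20 (adjusted p = 0.00204), the transcription factor gene ATF4 by 0.64 ± 0.08 (adjusted p = 0.00123) and HMOX1, heme oxygenase, by 0.90 ± 0.12 (adjusted p = 0.00204). These 3 calls were lost without E2 replicate 1 (0.105, 0.0895 and 0.0895), and those of ATF4 and HMOX1 also without E2+R4K1 replicate 2 (0.0646 and 0.0989). GREB1 (−0.15, adjusted p = 0.47), PGR (−0.26, 0.396), TFF1 (−0.24, 0.327), MYC (−0.07, 0.891), CCND1 (0.05, 0.799), CXCL12 (−0.14, 0.744), SIAH2 (−0.40, 0.0891) and ESR1 (−0.16, 0.369) were not called. Without R4K1 replicate 1 or 2, SIAH2 (0.00418 and 0.00422) and TFF1 (0.0436 and 0.0434) were called lower. In the 4 compared libraries alone SIAH2 (0.00114), TFF1 (0.0164) and PGR (0.0332) were, and DESeq2 called SIAH2 (0.0326).

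In E2+R4K1 against E2, the ATF4 list had 8 of 22 members higher and 14 not called (adjusted over the list alone, 11, with a median of 0.26, camera's adjusted p = 1.09e-09). The NRF2 list had 4 of 19 higher and 15 not called (adjusted over the list alone, 8, with a median of 0.11, adjusted p = 0.00044), and ribosome biogenesis 8 of 28 higher, 1 lower and 19 not called (adjusted over the list alone, 10 and 1, with a median of 0.12, adjusted p = 6.71e-05). Their calls passed with an estimated correlation (adjusted p = 0.0305, 0.0367 and 0.0367). The ATF4 list was lost without Vehicle replicates 1 and 2 (0.0604 and 0.0596), E2 replicate 2 (0.0963) or E2+R4K1 replicate 1 (0.104). The NRF2 list was lost without 10 of the 12 libraries (0.0564 to 0.135, with 0.102 for either R4K1 library) and kept without E2 replicate 1 or E2+R4K1 replicate 2. Ribosome biogenesis was lost without 9 (0.0564 to 0.104) and kept without E2 replicate 1 or either R4K1 library. The estrogen-induced list had 3 of 49 lower and 46 not called (adjusted over the list alone, 5, with a median of −0.15, adjusted p = 0.000386, and adjusted p = 0.264 with an estimated correlation). The estrogen-repressed list had 3 of 20 lower (adjusted over the list alone, 6 lower and 1 higher, with a median of −0.14, adjusted p = 0.00522, and adjusted p = 0.135 with an estimated correlation). The luminal list had 5 of 19 lower (adjusted over the list alone, 8 lower and 3 higher, with a median of −0.21, adjusted p = 0.00823, and adjusted p = 0.429 with an estimated correlation). Heat shock genes had 1 of 17 higher (adjusted over the list alone, 3, with a median of 0.17, adjusted p = 0.00257, and adjusted p = 0.0941 with an estimated correlation). DNA replication had 2 of 28 higher (adjusted over the list alone, 5, with a median of 0.08, adjusted p = 0.00553, and adjusted p = 0.264 with an estimated correlation, 0.0716 without E2+R4K1 replicate 1). Mitosis had 1 of 25 higher (adjusted over the list alone, 2, with a median of 0.12, adjusted p = 0.00823, and adjusted p = 0.317 with an estimated correlation, 0.201 without E2+R4K1 replicate 1). The endoplasmic reticulum stress list had 1 of 19 lower (adjusted over the list alone, 3, with a median of −0.04, adjusted p = 0.0452, and adjusted p = 0.526 with an estimated correlation). That call was lost without E2 replicates 1 and 2 (0.0737 and 0.0603), 4OHT replicates 1 and 2 (0.0588 and 0.0586) or E2+R4K1 replicate 2 (0.465). Of these 7 lists fry called estrogen-induced (adjusted p = 0.0498), estrogen-repressed (0.0147), heat shock (0.0164) and DNA replication (0.049), and none of the 4 without E2 replicate 1 (0.103 to 0.152), E2 replicate 2 (0.0651 to 0.188) or E2+R4K1 replicate 2 (0.0763 to 0.203).

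Between E2+R4K1 and E2 472 genes were called, 268 higher and 204 lower, with 12 and 7 at least 2-fold. The count was 4 and 93 without E2 replicates 1 and 2, and 313 and 5 without E2+R4K1 replicates 1 and 2. It was 259 to 267 without a 4OHT or E2+4OHT library, and 2037 and 2052 without R4K1 replicates. It was 2114 with the 4 compared libraries alone, 267 with no filter on low counts and 794 with DESeq2.

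In cells that had received R4K1, E2 still raised its targets. SDK2 rose by 2.81 ± 0.16 (adjusted p = 2.97e-08) over R4K1 alone and PGR by 2.02 ± 0.15 (adjusted p = 2.04e-07), the last from 213.9 ± 25.9 to 905.2 ± 46.8 scaled counts. GREB1 rose by 1.78 ± 0.09 (adjusted p = 1.68e-08), from 3335 ± 341 to 11913 ± 907, CXCL12 by 1.34 ± 0.16, SIAH2 by 1.14 ± 0.12, MYC by 0.94 ± 0.16 and CCND1 by 0.46 ± 0.08. TFF1 rose by 0.44 ± 0.12 (adjusted p = 0.0208), a call lost without R4K1 replicate 1 (0.0618) or E2+R4K1 replicates 1 and 2 (0.0985 and 0.129). In the 4 compared libraries alone TFF1 (0.172) and CCND1 (0.0914) were not called. The 645 genes raised by E2 without inhibitor had a median of 0.58, with 630 (97.7%) in the same direction and 474 called (fry's adjusted p = 4.75e-09). The 258 lowered genes had −0.41, with 252 in the same direction and 145 called (fry's adjusted p = 1.65e-05). Their choice on E2 against Vehicle favours large values in that comparison, so medians on a left-out replicate are given further on.

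The estrogen-induced list had 36 of 49 members higher and 13 not called with E2 after R4K1 (adjusted over the list alone, 37 higher and 1 lower, with a median of 0.79, camera's adjusted p = 2.86e-29, and adjusted p = 0.0238 with an estimated correlation). The last was above 0.05 without Vehicle replicates 1 and 2 (0.0553 and 0.0667), either E2+4OHT replicate (0.0564) or E2+R4K1 replicate 1 (0.0841). Camera's other calls were lost with an estimated correlation. The estrogen-repressed list had 7 of 20 lower and 1 higher (adjusted over the list alone, 7 and 2, with a median of −0.26, adjusted p = 0.00574, and adjusted p = 0.192 with an estimated correlation, 0.0565 without R4K1 replicate 1). Immediate early genes had 14 of 33 lower and 4 higher (adjusted over the list alone, 16 and 4, with a median of −0.32, adjusted p = 0.00347, and adjusted p = 0.481 with an estimated correlation). Ribosome biogenesis had 7 of 28 higher and 1 lower (adjusted over the list alone, 8 and 1, with a median of 0.17, adjusted p = 0.00319, and adjusted p = 0.138 with an estimated correlation). Lysosomal genes had 5 of 23 lower (adjusted over the list alone, 5, with a median of −0.11, adjusted p = 0.0274, and adjusted p = 0.481 with an estimated correlation, 0.438 without R4K1 replicate 2 and 0.0917 without E2+R4K1 replicate 2). The p53 list had 8 of 22 lower and 2 higher (adjusted over the list alone, 9 and 2, with a median of −0.14, adjusted p = 0.03, and adjusted p = 0.192 with an estimated correlation). Its call was lost without R4K1 replicates 1 and 2 (0.0699 and 0.0695) or E2+R4K1 replicate 2 (0.0561). Fry called the repressed (adjusted p = 0.00151), immediate early (0.0298), ribosome biogenesis (0.00144) and p53 (0.00144) lists and not lysosome (0.073). Its call of immediate early genes was lost without 7 of the 12 libraries (0.0557 to 0.131). In limma's test 2766 genes were called between E2+R4K1 and R4K1, 1244 higher and 1522 lower. Scaling by library totals gave 1763 and 1112. The count was 5629 without R4K1 replicate 1, 531 without E2+R4K1 replicate 2, 2404 without R4K1 replicate 2, and 352 with the 4 compared libraries alone.

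**Figure D3:**
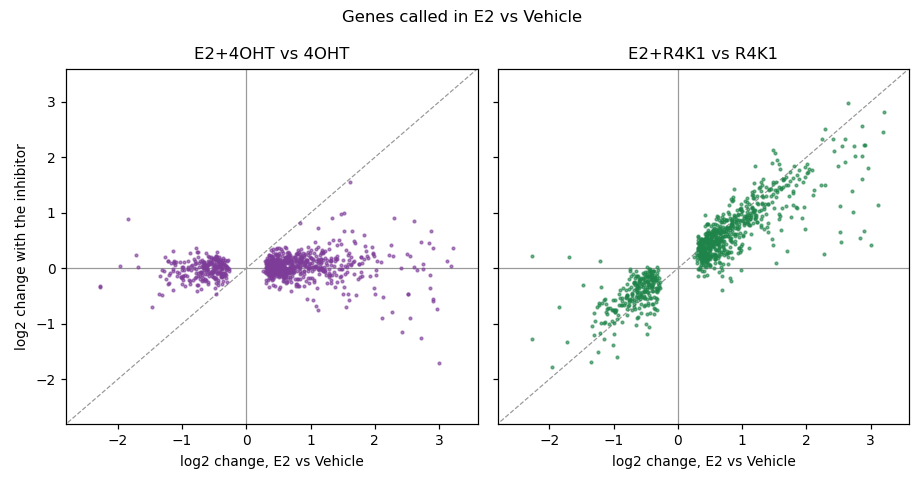
Log2 change with E2 in the presence of each inhibitor (y axis; left E2+4OHT against 4OHT, right E2+R4K1 against R4K1) against the log2 change of E2 against Vehicle (x axis), for the genes called in E2 against Vehicle, with a dashed line where the 2 are equal. The 645 raised genes had a median of 0.68 without inhibitor, 0.05 with 4OHT and 0.58 with R4K1.

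No gene was called for a difference between the E2 responses with and without R4K1. The interaction of PGR was −0.84 (95% interval −1.28 to −0.4, adjusted p = 0.428), that of SIAH2 −0.65 (−1.02 to −0.28, 0.428), of MYC −0.65 (−1.12 to −0.18, 0.428), and of TFF1 −0.44 (−0.81 to −0.08, 0.456). It was −0.32 for GREB1 (−0.6 to −0.03, 0.482), −0.15 for CCND1 (−0.38 to 0.08, 0.661), −0.14 for CXCL12 (−0.61 to 0.33, 0.859) and 0.29 for ESR1 (0.05 to 0.54, 0.468). The intervals are not corrected for the number of genes and do not show that the responses were alike. Without R4K1 replicate 1, PGR (0.00467), GREB1 (0.0214), TFF1 (0.00123), MYC (0.0499), SIAH2 (0.000573) and ESR1 (0.0112) were called. The estrogen-induced list had a median interaction of −0.25 with 0 of 49 members called (adjusted over the list alone, 14 lower; camera's adjusted p = 3.73e-10, and adjusted p = 0.222 with an estimated correlation). Limma called 0 genes, with 1688 at an unadjusted p under 0.05 and a smallest adjusted p of 0.184. EdgeR called 0 genes and DESeq2 4. Limma called 2338 genes without R4K1 replicate 1 and 6 without R4K1 replicate 2.

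The E2 response was also measured on replicates that had no part in choosing the genes. Genes that rose at least 2-fold in replicate 1 of E2 against Vehicle, 148 in number, had a median of 1.24 in replicate 2, of 1.16 in E2+R4K1 against R4K1 and of 0.07 in E2+4OHT against 4OHT. With the replicates exchanged, 144 genes had medians of 1.3, 1.16 and 0.10. Of these genes 70.9% and 67.4% had a smaller response with R4K1 than in the left-out replicate, against 62.9% and 54.5% of lowered genes. For 35 and 33 genes that fell at least 2-fold, the medians were −0.85 and −0.97 in the left-out replicate, −0.71 and −0.83 with R4K1, and −0.09 and −0.13 with 4OHT. No test was run on these medians.

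The inhibitors were then set against each other, with the stated difference in dose and time. Without E2, GREB1 stood 1.15 ± 0.09 higher with R4K1 than with 4OHT (adjusted p = 9.29e-07) and PGR 0.91 ± 0.15 higher (adjusted p = 0.000801). CYP1A1 stood at −7.32 ± 0.39, CYP1B1 at −4.10 ± 0.17, CHAC1 at −2.60 ± 0.19 and HMGCS1 at −1.57 ± 0.08 (adjusted p = 1.5e-08). Cholesterol synthesis genes were lower with R4K1 in 19 of 25 cases and 6 were not called (adjusted over the list alone, 22, with a median of −0.85, camera's adjusted p = 9.11e-26). ATF4 genes were lower in 14 of 22 cases and 8 were not called (adjusted over the list alone, 16 lower and 1 higher, with a median of −0.62, adjusted p = 2.23e-18). Endoplasmic reticulum stress genes were lower in 15 of 19 cases and 4 were not called (adjusted over the list alone, 17, with a median of −0.58, adjusted p = 1.1e-17). Aryl hydrocarbon receptor genes were lower in 6 of 9 cases and 3 were not called (adjusted over the list alone, 7, with a median of −0.82, adjusted p = 2.04e-09). DNA replication genes were higher (12 of 28, 1 lower, 15 not called, and adjusted over the list alone, 16 and 1; median 0.28, adjusted p = 5.66e-09). An estimated correlation left these 5 lists called (adjusted p between 0.00282 and 0.0268). There endoplasmic reticulum stress was lost without either E2 replicate (0.0514), 4OHT replicate 2 (0.0703) or R4K1 replicate 1 (0.14). DNA replication was lost without either E2 replicate (0.0514), either E2+R4K1 replicate (0.0519) or R4K1 replicate 1 (0.155), and the aryl hydrocarbon receptor list without R4K1 replicate 1 (0.085). Limma called 1920 genes, 759 higher and 1161 lower with R4K1. Scaling by library totals gave 523 and 1387. The count was 423 and 1057 without 4OHT replicates 1 and 2, 5448 without R4K1 replicate 1 and 295 with the 4 compared libraries alone.

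With E2 present, PGR stood 3.05 ± 0.15 higher with R4K1 than with 4OHT (adjusted p = 1.76e-09), GREB1 2.81 ± 0.09 higher (adjusted p = 2.58e-11), CXCL12 1.90, SIAH2 1.39, TFF1 1.04 ± 0.12, MYC 1.03 and CCND1 0.58 higher. CYP1A1 stood at −6.67 ± 0.39, CHAC1 at −2.84 ± 0.19 and HMGCS1 at −1.71. Of 49 estrogen-induced genes 34 were higher, 4 lower and 11 not called (adjusted over the list alone, 39 and 4, with a median of 0.86, camera's adjusted p = 5.53e-26). Of 28 DNA replication genes 11 were higher and 17 not called (adjusted over the list alone, 17 higher and 1 lower, with a median of 0.25, adjusted p = 3.28e-07). Ribosome biogenesis was higher as well (15 of 28, 13 not called, and adjusted over the list alone, 17; median 0.37, adjusted p = 8.59e-10). Cholesterol synthesis genes were lower in 20 of 25 cases and 5 were not called (adjusted over the list alone, 21, with a median of −0.95, adjusted p = 7.81e-24). ATF4 genes were lower in 16 of 22 cases and 6 were not called (adjusted over the list alone, 17 lower and 1 higher, with a median of −0.72, adjusted p = 9.98e-16). Endoplasmic reticulum stress genes were lower in 16 of 19 cases and higher in 1 (adjusted over the list alone, 17 and 1, with a median of −0.65, adjusted p = 8.35e-14), and aryl hydrocarbon receptor genes lower in 6 of 9 (adjusted over the list alone, 6, with a median of −0.55, adjusted p = 6.79e-07). With an estimated correlation these 7 lists were called too (adjusted p between 0.00452 and 0.0305). There endoplasmic reticulum stress was lost without either E2 replicate (0.052) or either 4OHT replicate (0.0534), and DNA replication without either E2 replicate (0.052), E2+4OHT replicate 2 (0.056) or E2+R4K1 replicate 1 (0.0782). Limma called 3036 genes, 1511 higher and 1525 lower. Without replicates 1 and 2 in turn the count was 1325 and 1419 (E2+4OHT), 1873 and 1336 (E2+R4K1) and 4835 and 4838 (R4K1), and it was 5039 with the 4 compared libraries alone.

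**Figure D4:**
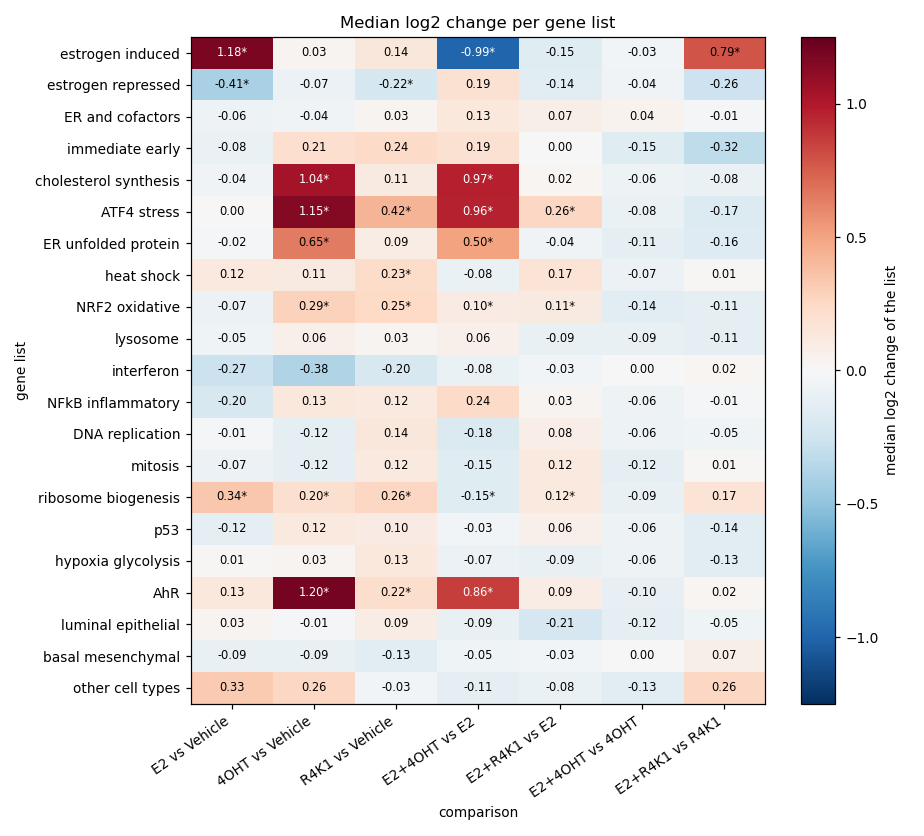
Median log2 change of each gene list (vertical axis) in 7 comparisons (horizontal axis) as a colour scale, with an asterisk where camera's adjusted p was below 0.05 with an estimated correlation. The ATF4 list had medians of 1.15 with 4OHT and 0.42 with R4K1 against Vehicle.

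Against Vehicle, 61 genes were called higher with both 4OHT and R4K1 (ATF3, CHAC1 and GDF15 among them) and 30 lower with both (IGFBP5 among them). Independent lists would share 7 and 3.88. In 8 genes 4OHT was higher and R4K1 lower, and in 0 the reverse. With E2, 47 genes were higher and 53 lower with both inhibitors against E2 alone, where independent lists would share 17 and 10.6. In 11 genes E2+4OHT was higher and E2+R4K1 lower, and in 4 the reverse. Simulations of unchanged groups shared at most 2 and 0 (1 and 1 with E2). With no gene changed, that is no chance level. The changes correlated at 0.386 and, with E2, 0.345 (simulated 0.498 and 0.502), with covariances of 0.0541 and 0.0492 (simulated 0.0353 and 0.0357). Part of the excess may come from the shared controls, which were too few to split. Without 1 library the 91 against Vehicle became 9 (Vehicle replicate 1) to 528 (R4K1 replicate 1), and the 100 against E2 became 3 (E2 replicate 1) to 498 (R4K1 replicate 2).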

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

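Here the tests of depth and of a mislabelled library were set before their results were seen, with bounds from medians already known. Those of scaling, 4OHT alone, R4K1 replicate 2 alone, 24 h handling and RNA classes were chosen after the result was seen.

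The response to E2 differed with and without 4OHT by the interaction test in 388 genes. The interaction was −2.98 for PGR, −2.85 for SDK2, −2.77 for FOXC1, −2.66 for EGR3, −2.64 for SNAI1, −2.58 for PTGES, −2.54 for KCNK5, −2.42 for THSD4-AS1, −2.33 for LINC00673 and −2.20 for HSPB8. It was −2.16 for MYC, −1.98 for GREB1, −1.86 for SIAH2, −1.61 for CXCL12, −1.05 for TFF1 and −0.74 for CCND1. On the other side it was 1.92 for TNFRSF11B, 1.47 for PDE4B, 1.34 for GABRB2, 1.26 for RNF43, 1.22 for TMEM150C and NTN4, 1.21 for BTG2 and ID2, 1.17 for LIN7A and 1.15 for ATP8A1. Calls were lost without E2+4OHT replicate 1 for BTG2 (adjusted p = 0.054), ATP8A1 (0.0512) and NTN4 (0.0748), for NTN4 also without Vehicle replicate 1 (0.0635), E2 replicate 2 (0.0763) or 4OHT replicate 2 (0.0758). That of GABRB2 was lost without any 1 of the 8 libraries in the interaction (Vehicle 0.107 and 0.0636, E2 0.0896 and 0.0768, 4OHT 0.0819 and 0.0988, E2+4OHT 0.0871 and 0.0844). That of PDE4B was lost without Vehicle 1 and 2 (0.0609 and 0.159), E2 1 (0.201), 4OHT 1 and 2 (0.0755 and 0.163) or E2+4OHT 1 and 2 (0.148 and 0.115).

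Gene lists also differed in their E2 response with and without 4OHT by camera's interaction test. The medians were −1.18 for the estrogen-induced and −0.46 for the ribosome biogenesis list, both called with an estimated correlation too. The estrogen-repressed list had 0.18 (adjusted p = 0.135 with an estimated correlation), endoplasmic reticulum stress −0.11 (0.449; lost without Vehicle replicate 1 at 0.162), and interferon 0.27 (0.155; lost without Vehicle replicate 1 at 0.162 and 4OHT replicate 2 at 0.108). Heat shock had −0.19 (0.155; lost without Vehicle 1 at 0.162, E2 2 at 0.0574, 4OHT 2 at 0.0926 and E2+4OHT 2 at 0.0662) and the aryl hydrocarbon receptor list −0.19 (0.155; lost without Vehicle 1 at 0.167, 4OHT 1 at 0.0537 and E2+4OHT 1 at 0.0633).

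With and without R4K1, 8 lists differed in their E2 response by camera with the preset correlation, and no call held with an estimated one (adjusted p between 0.222 and 0.468). The medians were −0.25 for the estrogen-induced list, −0.29 for immediate early genes and −0.23 for ATF4 genes (lost without Vehicle replicate 2 at 0.0778). Endoplasmic reticulum stress had −0.21 (lost without Vehicle 1 at 0.0593), interferon 0.16 (lost without Vehicle 1 at 0.0863, E2 2 at 0.0548 and R4K1 1 at 0.163), ribosome biogenesis −0.11 (lost without Vehicle 2 at 0.0867, R4K1 1 at 0.595 and E2+R4K1 1 at 0.115), hypoxia −0.13 (lost without R4K1 2 at 0.0892) and luminal genes −0.16 (lost without Vehicle 1 at 0.0506 and R4K1 2 at 0.331).

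The smaller estrogen-list response after 4OHT was weighed first. Lower depth of the 4OHT libraries is argued against, since the median interaction was −1.17 after all libraries were thinned to 15929818 reads. Scaling is argued against, since the median nearest to 0 under other factors was −1.15. A rise of the list with 4OHT alone that leaves no room for E2 is argued against, since that median was 0.03. That 4OHT at the receptor kept E2 from inducing these genes stays open as a hypothesis, as does the longer time with 4OHT in E2+4OHT, and no test of either was run.

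The rise of ATF4-list genes with R4K1 was weighed next. R4K1 replicate 2 alone is argued against as its source, since the median without it was 0.42 (camera's adjusted p = 1.31e-15). Scaling is argued against, since the lowest median under other factors was 0.36. The number of groups stated to have been handled for 24 h without the peptide was 0, so 24 h of exposure or handling and the peptide itself cannot be told apart. The peptide or the longer handling may account for the rise.

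The spread between the R4K1 replicates was weighed last. Differing shares of ribosomal, small nucleolar, small nuclear and histone genes are argued against as the whole cause, since the SD between the replicates without these genes was 0.367, against at most 0.28 in the other groups. Lower depth is argued against, since the SD after thinning was 0.385, against at most 0.285. A library of another of the 6 groups under the wrong label is argued against, since 0 other groups held the values of R4K1 replicate 2 for the estrogen-induced, ATF4 and aryl hydrocarbon receptor lists together. A difference in culture, RNA or library preparation stays open as untested, and no biological explanation was tested.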

How the results depend on the processing

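The pseudocounts, edgeR on recovered reads, the removal of RNA classes and the recomputing of lists and overlaps under each setting were chosen after the results were seen, while the other alternatives were planned.

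Of 598 named gene values (424 called) 0 reversed sign past the threshold in any alternative. Of these 335 kept their side in every setting (278 called). Library totals turned E2+R4K1 against R4K1 from mostly lower to mostly higher calls. RLE factors, either pseudocount, every deposited entry, edgeR on recovered reads and the removal of RNA classes left each count of calls within 1.5 times its value. Depth limits what low genes can show, and with 2 replicates per group limma recovered 42% of simulated 1.5-fold changes for E2 against Vehicle. Except where stated, the cause of a change below was not tested.

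Leaving out 1 library at a time gave counts of calls from 445 to 1660 (E2), 496 to 2985 (4OHT) and 11 to 3402 (R4K1) against Vehicle. Against E2 they ran from 1000 to 3501 (E2+4OHT) and 4 to 2052 (E2+R4K1), and against 4OHT from 0 to 52 (E2+4OHT) and 423 to 5448 (R4K1). They ran from 531 to 5629 for E2+R4K1 against R4K1, 1325 to 4838 for it against E2+4OHT, and 195 to 863 and 0 to 2338 for the interactions with 4OHT and R4K1. Fewer libraries lower the count by construction, and leaving out an R4K1 library removes that pair from the shared spread. Overlaps ranged from 3 to 498 with E2 and from 9 to 528 without. With E2 after 4OHT, E2-raised genes had medians from 0.03 to 0.09 and E2-lowered genes from −0.03 to 0.02.

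Of 131 uncalled list results camera called 25 in at least 1 of the same fits, 0 of them with an estimated correlation there. For R4K1 against Vehicle these included lysosome (0.16, adjusted p = 0.0376), hypoxia (0.15, 0.0297), luminal (0.20, 0.0393) and basal and mesenchymal genes (−0.34, 0.0169) without R4K1 replicate 1. Without R4K1 replicate 2 they included heat shock (0.11, 0.0223) and ribosome biogenesis (0.07, 0.0133) for R4K1 against 4OHT, and mitosis for E2+R4K1 against R4K1 (−0.17 from 0.01, 0.00253, fry's 0.00929). Without E2+R4K1 replicate 1 immediate early genes were called for E2+R4K1 against E2+4OHT (−0.31 from −0.21, 0.00968, fry's 0.00185). Over the same fits, medians of lists that lost their call ranged as follows. For E2 against Vehicle they were −0.33 to −0.18 (interferon) and −0.16 to −0.04 (p53), and for 4OHT against Vehicle 0.08 to 0.13 (heat shock). For R4K1 against Vehicle they were 0.02 to 0.24 (estrogen-induced), 0.10 to 0.14 (cholesterol), −0.33 to −0.17 (interferon), 0.03 to 0.24 (mitosis) and 0.14 to 0.39 (aryl hydrocarbon receptor). For E2+4OHT against E2 immediate early genes had 0.08 to 0.28. For E2+R4K1 against E2 they were −0.13 to −0.02 (endoplasmic reticulum stress), 0.04 to 0.12 (DNA replication) and 0.10 to 0.15 (mitosis). For E2+4OHT against 4OHT they were −0.11 to −0.05 (heat shock), −0.10 to −0.02 (lysosome), −0.11 to −0.04 (DNA replication), −0.09 to −0.02 (p53) and −0.17 to −0.07 (luminal). For E2+R4K1 against R4K1 they were −0.36 to −0.23 (estrogen-repressed), −0.21 to −0.11 (lysosome) and −0.18 to −0.08 (p53). For the interaction of E2 with 4OHT they were −0.16 to −0.06 (endoplasmic reticulum stress), −0.22 to −0.13 (heat shock), 0.18 to 0.40 (interferon) and −0.27 to −0.11 (aryl hydrocarbon receptor). For that with R4K1 they were −0.23 to −0.17 (ATF4), −0.28 to −0.09 (endoplasmic reticulum stress), 0.08 to 0.30 (interferon), −0.13 to −0.05 (ribosome biogenesis), −0.20 to −0.10 (hypoxia) and −0.32 to −0.05 (luminal). For R4K1 against 4OHT they were −0.26 to −0.18 (estrogen-repressed), −0.21 to −0.08 (NRF2) and 0.14 to 0.35 (mitosis).

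With only the groups compared in the fit, limma's counts rose without the R4K1 group and fell with it. Its wider spread would do this, and fewer samples alone would not. The counts were 1655 (E2) and 2315 (4OHT) against Vehicle, 4935 (E2+4OHT) and 2114 (E2+R4K1) against E2, and 337 for E2+4OHT against 4OHT. They were 947 for the interaction with 4OHT, 5039 for E2+R4K1 against E2+4OHT, 4 and 295 for R4K1 against Vehicle and 4OHT, and 352 for E2+R4K1 against R4K1. The overlaps were 736 with E2 and 3 without. E2-raised genes had a median of 0.04 after 4OHT (fry's unadjusted p = 0.153) and E2-lowered genes −0.03 (0.0106). DESeq2 called 499 genes for R4K1 against Vehicle, 794 for E2+R4K1 against E2, 3 for E2+4OHT against 4OHT and 4 for the interaction with R4K1, with overlaps of 156 and 143. With no filter, which tests 23004 genes, the counts were 135 for R4K1 against Vehicle and 267 for E2+R4K1 against E2, with overlaps of 58 and 51. Gene lists were not run with DESeq2, with edgeR or on only the groups compared.

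With the filter at 5 CPM, which tests fewer genes, camera lost its call for interferon (−0.08) and p53 (−0.12) in E2 against Vehicle, heat shock in 4OHT against Vehicle (0.11), interferon in R4K1 against Vehicle (−0.14) and endoplasmic reticulum stress in E2+R4K1 against E2 (−0.03). It also lost heat shock (−0.05), lysosome (−0.08), DNA replication (−0.04), p53 (−0.04) and luminal genes (−0.10) in E2+4OHT against 4OHT, lysosome (−0.10) and p53 (−0.15) in E2+R4K1 against R4K1, interferon in both interactions (0.28 with 4OHT, 0.11 with R4K1) and ribosome biogenesis in that with R4K1 (−0.09). With library totals it lost heat shock in 4OHT against Vehicle (0.09), heat shock (−0.03), lysosome (−0.05), DNA replication (−0.02), p53 (−0.02) and luminal genes (−0.08) in E2+4OHT against 4OHT, and interferon (0.22) and ribosome biogenesis (−0.06) in the interaction with R4K1. The uncalled median of E2-lowered genes after 4OHT was 0.03 with library totals and 0.02 with that filter.

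Replicate numbers are shared between groups, and same-numbered samples did not deviate together: over 15 pairs of groups the correlation of deviations ran from −0.06 to 0.06. With the replicate number as a block each count of calls was within 1.5 times its value. The endoplasmic reticulum stress list in E2+R4K1 against E2 had −0.04 with the block (camera's adjusted p = 0.0505), and no other count, median or list call changed. Of the named gene values, 5 calls were lost with it.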

Other observations

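The gene lists and the counts of called genes with a library left out were fixed in advance. The recomputing of lists with a library left out, the estrogen-list interaction by fry and the count of additional calls with R4K1 were chosen after the results were seen.

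Genes of the estrogen receptor and its cofactors moved in both directions with E2. Of 18 measured, 4 rose and 3 fell (adjusted over the list alone, 5 and 6, with a median of −0.06, camera's adjusted p = 0.838). NRIP1, a corepressor induced by the receptor, rose by 1.49 ± 0.12 and the transcription factor gene TFAP2C by 1.19 ± 0.08, while the coactivator gene NCOA2 fell by 0.59 and the luminal factor gene GATA3 by 0.44 on the log2 scale. These 4 genes were outside the rule for named genes and were chosen after their values were seen, so their values were not recomputed with a library left out. With R4K1 alone 0 rose and 2 fell (adjusted over the list alone, 2 and 3, with a median of 0.03, adjusted p = 0.894). It was 4 and 4 without R4K1 replicate 1, and 0 and 2 without R4K1 replicate 2. With E2+R4K1 against E2 0 of 18 were called in limma (adjusted over the list alone, 0, with a median of 0.07, adjusted p = 0.585). Inflammatory genes (17 measured), basal and mesenchymal genes (11) and markers of other cell types (6) were called by camera in none of the 11 comparisons with all libraries. Against Vehicle their medians with R4K1 were 0.12, −0.13 and −0.03, with 0, 1 and 0 members called. Basal and mesenchymal genes had −0.34 without R4K1 replicate 1, with 3 lower (camera's adjusted p = 0.0169, fry's 0.0082, and adjusted p = 0.15 with an estimated correlation), and 0.07 without R4K1 replicate 2 (camera's adjusted p = 0.919).

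Cell cycle genes differed between the inhibitors. With E2 present, 10 of 25 mitosis genes stood higher with R4K1 than with 4OHT and 0 lower (adjusted over the list alone, 10, with a median of 0.26, camera's adjusted p = 1.58e-05, and adjusted p = 0.0957 with an estimated correlation), among them the topoisomerase gene TOP2A at 0.65. Without R4K1 replicate 1 or 2 the estimated-correlation test called the list (0.0202 and 0.02), with 14 members higher in each case. Without E2, 10 were higher and 0 lower (adjusted over the list alone, 11, with a median of 0.24, adjusted p = 9.95e-06, and adjusted p = 0.117 with an estimated correlation, 0.112 by camera without R4K1 replicate 1). Without R4K1 replicate 2 the list had 13 members higher and a median of 0.35 (adjusted p = 0.00584 with an estimated correlation), and without R4K1 replicate 1 10 higher, 5 lower and one of 0.14 (0.37). Fry called the list with E2 (0.0034) and without it (0.0127), the latter not without 4OHT replicate 1 or 2 (0.0691 and 0.0506). Against E2 alone, E2+4OHT had 4 of 28 DNA replication genes lower and 1 higher (adjusted over the list alone, 6 and 1, with a median of −0.18, adjusted p = 0.000359, and adjusted p = 0.09 with an estimated correlation) and 2 of 25 mitosis genes lower (adjusted over the list alone, 1, with a median of −0.15, adjusted p = 0.00367, and adjusted p = 0.247 with an estimated correlation). Fry's adjusted p was 0.00288 and 0.0442, the second lost when Vehicle replicate 1 (0.0842) or any E2, 4OHT or E2+4OHT library (0.0707 to 0.18) was left out.

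Camera called other lists in E2+4OHT against E2 with the preset correlation and not with an estimated one, and fry called all 3 (adjusted p = 0.00151, 0.027 and 0.000263 in the order below). Fry lost immediate early genes when any E2, 4OHT or E2+4OHT library was left out (0.0557 to 0.302). The estrogen-repressed list had 6 of 20 higher and 2 lower (adjusted over the list alone, 7 and 3, with a median of 0.19, adjusted p = 0.0149, and adjusted p = 0.124 with an estimated correlation). Immediate early genes had 11 of 33 higher and 5 lower (adjusted over the list alone, 14 and 6, with a median of 0.19, adjusted p = 0.0158, and adjusted p = 0.458 with an estimated correlation, 0.0562 without E2 replicate 2). The p53 list had 8 of 22 higher and 1 lower (adjusted over the list alone, 8 and 2; adjusted p = 0.0148, and adjusted p = 0.0879 with an estimated correlation), with a mean of 0.22 and a median of −0.03, so the mean and the test differ in sign from the median.

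In E2+4OHT against 4OHT camera called 10 lists lower with 0 members called, and none held with an estimated correlation (adjusted p between 0.103 and 0.408). The medians were −0.15 for immediate early, −0.14 for NRF2, −0.12 for mitosis and luminal, −0.11 for endoplasmic reticulum stress, −0.09 for lysosome and ribosome biogenesis, −0.07 for heat shock and −0.06 for DNA replication and p53 genes. The estrogen-induced list had −0.03 (adjusted p = 0.379). Fry called NRF2 genes alone of the 10 lists (0.0258), and not without 8 of the 12 libraries (0.0564 to 0.221).

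Further lists differed between the inhibitors. With R4K1 against 4OHT the estrogen-repressed list had a median of −0.24 (5 of 20 lower, 1 higher; adjusted over the list alone, 7 and 1; adjusted p = 0.00579, and adjusted p = 0.11 with an estimated correlation; lost without 4OHT replicate 2 at 0.072 and R4K1 replicate 1 at 0.0501) and the NRF2 list one of −0.17 (6 of 19 lower; adjusted over the list alone, 7; adjusted p = 0.00579, and adjusted p = 0.0536 with an estimated correlation; lost without R4K1 replicate 1 at 0.0644). The estimated-correlation test called the first without 4OHT replicate 1 (0.0351). With E2 present these lists had −0.32 (adjusted p = 3.02e-05, and 0.0305 with an estimated correlation) and −0.15 (adjusted p = 0.00749, and 0.0453 with an estimated correlation). The estimated-correlation call of the first was lost without Vehicle replicate 2 (0.0509) or R4K1 replicate 1 or 2 (0.104 and 0.103), and that of NRF2 whichever of the 12 libraries was left out (0.054 to 0.108, the highest for either R4K1 library). Fry called both lists without E2 (0.00315 and 0.000107) and with it (8.4e-05 each). With E2 present, heat shock genes had a median of 0.16 (adjusted p = 0.00923, and adjusted p = 0.0792 with an estimated correlation, 0.00207 by fry).

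With all 12 libraries, 2766 genes were called for E2 with R4K1 and 903 without it. The order was the other way round in the 4 compared libraries alone (352 and 1655) and without E2+R4K1 replicate 2 (531 and 796). Of 2147 genes called for E2 only with R4K1, 1925 (89.7%) had the same sign in E2 against Vehicle. That choice favours the larger median absolute log2 change with R4K1 (0.45 against 0.15). The counts and this share do not test a difference between the responses, for which limma called 0 genes.

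A hypothesis was tested that R4K1 may make the response of the estrogen-induced list to E2 smaller. Its median interaction was −0.25, between −0.32 and −0.19 over the alternatives. Fry's adjusted p was 0.0831 with all libraries, 0.00377 without R4K1 replicate 1, 0.0374 without R4K1 replicate 2, and between 0.055 and 0.253 under the other alternatives. Camera's adjusted p with an estimated correlation was 0.222, 0.144 and 0.137 in these 3 fits. A smaller response and no difference cannot be told apart with 2 replicates per group, since the outcome changed with the test and with the R4K1 libraries in the fit.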
